A study of Mus musculus with 8 samples.

How the data were processed

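The series holds 8 mouse samples. RNA was sequenced from whole testes at postnatal day 8 (P8) in 6 libraries, 3 from wild-type animals and 3 from animals null for Dmrt6, the gene listed in the table as Dmrtb1. The design text calls the 3 libraries of a genotype biological replicates. The remaining 2 samples are 1 chromatin immunoprecipitation (ChIP) library made with a rabbit polyclonal antibody to DMRT6 and 1 input library, both from adult wild-type testis.

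The expression values are log2 CPM (counts scaled to library size), deposited by the authors in 1 table of 22744 Ensembl genes with their coordinates. The submitters' processing notes list STAR 2.3.0e, Bowtie2, Picard, edgeR and the genome build mm9, without saying which step each served. The read counter, the gene annotation release and any use of strand are not given in the sources used here. Every library has the same lowest value, and above that floor 2 to the power of the value rises in steps of one size per library. Whole reads were recovered from these steps: 100% of values came out whole at a tolerance of 1e-06, and the prior added before the log averaged 0.25 reads. The recovered reads in the table came to 23.8, 29.0 and 27.5 M in wild-type replicates 1, 2 and 3, and to 26.2, 27.4 and 26.3 M in null replicates 1, 2 and 3. At that depth a count of 0 allows up to 3 reads, or 0.109 CPM in wild-type replicate 3. Such limits, and the intervals on peak counts, cover counting error only.

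The ChIP peaks are a list of 14862 regions, each with a score, called by the authors on the single ChIP library with the single input library. Per the labels, that file belongs to both libraries. The file name gives MACS 1.4 as the caller and removal of duplicate reads. The lowest score is 50.02, and no header states the scale. The score is the authors' own value and was used only to describe, rank and filter peaks. The read depth of the ChIP and input libraries is unknown from the files used here, and with 1 library each there is no replicate check on any peak.

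Coordinates are given as in the files, 1-based, in mm9. A check against the gene table of another build, GRCm38, placed 181 genes beyond its last gene on their chromosome, 143 of them on chromosome 7, and 826 of 18724 shared symbols ended within 1 kb of the same position, so that build was not used for positions. A gene's 5' end, the outer end of its coordinates in the expression table, stood in for its transcription start site. That table has 1 start and 1 end per gene, so alternative starts, exons, introns and untranslated regions were not distinguished. A gene counted as bound when a peak's middle lay within 10 kb of its 5' end.

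Genes entered the tests with a mean over the 6 libraries of at least 0 on the log2 CPM scale, which left 16634. The test was limma-trend (limma 3.58.1 in R 4.3.3) with genotype as the only term and no pseudocount beyond the authors' own, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so none was used for single genes. All changes are log2 CPM in null minus wild type, and errors are standard errors (SE) of the limma model unless given as SD. The edgeR and DESeq2 alternatives planned for recovered counts were not run, although whole reads were recovered. limma's voom on the recovered reads was added after the files were seen. Tested on simulated data with the same 16634 genes, the limma test recovered 46% of 100 genes changed by 1 log2 unit. It recovered 92% of 100 changed by 2, and 9 of its 147 calls were unchanged genes. With that many calls a gene passes the adjustment more easily than where few genes change. The simulated libraries also had no shared structure beyond genotype and depth. These shares may therefore overstate what the test could find in the real libraries.

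A set of 20 gene lists was fixed before the data were examined: germ cell stages (undifferentiated and differentiating spermatogonia, meiotic entry and prophase, pachytene and later cells), the DMRT family, the piRNA pathway, Sertoli, Leydig, peritubular and stromal, and endothelial cells, macrophages and leukocytes, red blood cells, epididymis and rete, the mitotic cell cycle, the retinoic acid pathway, p53 targets and apoptosis, immediate early genes, X-linked germ cell genes, Y-linked genes and core histones. Each was tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. The tests, their samples, the window of 10 Mb around Dmrtb1, the lists, the named-gene rule and most alternatives were set before the data were examined.

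Genes are named by this rule: Dmrtb1 first, then genes past the threshold with no overlap between genotypes, then, where fewer than 12 pass in a direction, those of smallest unadjusted p up to 6 per direction, and up to 4 members of smallest p in each list. Symbols made of Gm and digits, ending in Rik or starting with LOC, and genes without a symbol, are counted but passed over. The single gene past the threshold had such a symbol and is named, as are its neighbours on chromosome 4, as chosen after their values were seen. Peaks named are the 10 of highest score and those within 10 kb of the 5' end of Dmrtb1, Kit, Sohlh1, Sohlh2, Stra8, Dmrt1 and the named gene past the threshold. The 12 genes of smallest p kept by this rule and some list members were looked up in addition.

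The share of peak middles within 1 kb of a 5' end was compared with 100 seeded random placements of the same peaks on the same chromosomes, between the first and last feature there. Shares have exact 95% binomial intervals and peak densities exact 95% Poisson intervals. Alternatives covered the expression filter, a pseudocount of 1 CPM, quantile normalization, median centring, the variance model, array weights, the replicate number as a block, each library left out in turn, other windows, other distances and stricter peak scores. A planned search for the DMRT core motif in the peaks was not run, since no mm9 genome sequence was used here. Figures were drawn with matplotlib 3.10.9.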

Results

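DMRT6, encoded by Dmrtb1, is a DNA-binding protein of the doublesex and mab-3 related (DMRT) family found in male germ cells. The study asked which transcripts depend on it in the P8 mouse testis, when spermatogonia are differentiating and meiosis is about to begin, and where the protein binds in the adult testis. The expression data comprised 3 wild-type and 3 Dmrt6 null libraries with 23.8 to 29.0 M reads each in the deposited table. The binding data comprised 14862 peaks from 1 ChIP library with 1 input library.

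Dmrtb1 itself (ENSMUSG00000028610, chromosome 4, 107348895 to 107356835, minus strand, mm9) was lower in each of the 3 null libraries than in any wild-type library. Its log2 CPM was 3.03, 4.12 and 3.21 in wild-type replicates 1, 2 and 3 and -0.88, -0.13 and 0.03 in null replicates 1, 2 and 3. The recovered reads were 194, 510 and 254 against 14, 25 and 26. The mean was 3.45 ± 0.59 (SD, n = 3) in wild type and -0.33 ± 0.49 (SD, n = 3) in null, a difference of -3.78 (SE 0.36), or a level of 0.0727 times wild type. In limma, with adjustment over all 16634 genes, the adjusted p was 0.0516, just short of the threshold. It was 4.97e-05 when adjusted over the DMRT family list alone. Quantile normalization gave an adjusted p of 0.0256 and median centring one of 0.00678, over a range of 7.74e-05 to 0.289 for all alternatives. Leaving out null replicate 3 gave 0.0182.

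**Figure D1:**
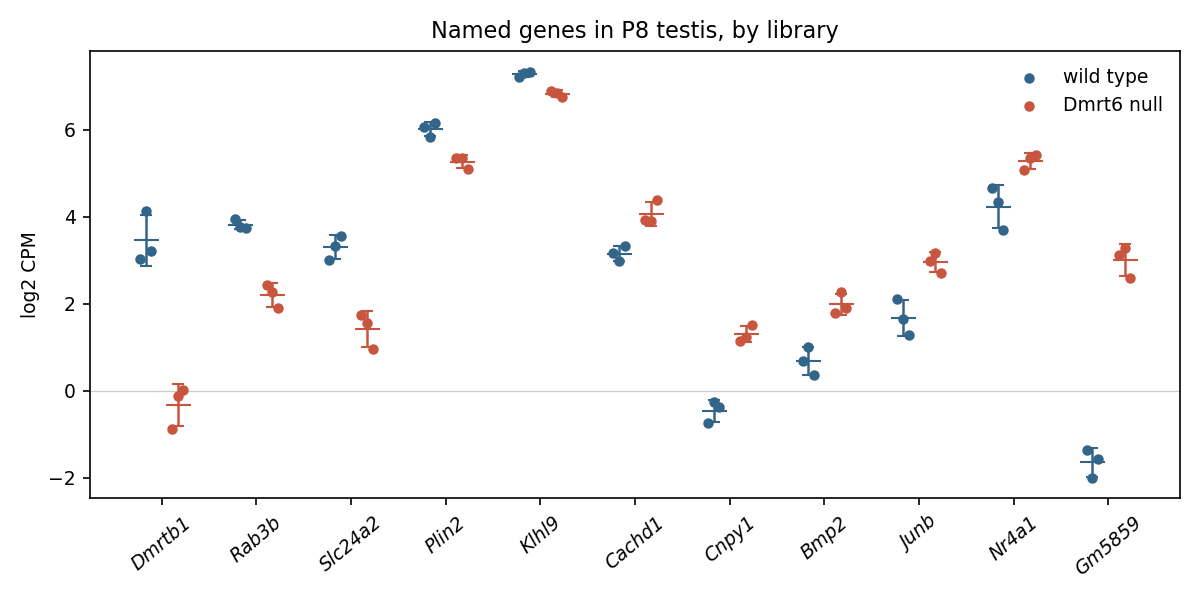
Log2 CPM of 11 named genes in each P8 library, with the mean and SD (n = 3) per genotype drawn as bars. Dmrtb1 lay at 3.03 to 4.12 in wild type and at -0.88 to 0.03 in null, and Gm5859 is the gene past the threshold.

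Few genes passed the threshold between the genotypes. The test recovered 46% of simulated genes changed by 1 log2 unit, but there it made 147 calls, so its power here may be lower. limma placed 1 gene past the threshold, Gm5859 (ENSMUSG00000073879, chromosome 4, 42107582 to 42109905), a predicted gene with log2 CPM of -1.65 ± 0.33 in wild type and 3.00 ± 0.37 in null (SD, n = 3). It rose by 4.65 (SE 0.30, adjusted p = 0.00458), from 9, 7 and 9 reads to 229, 269 and 154. At an adjusted p of 0.1 the count was 3 genes, 2 higher and 1 lower in null. An unadjusted p below 0.05 was found for 578 genes, 271 higher and 307 lower, where chance alone would give 832. That count rested on single libraries: it was 2547 without null replicate 2, 267 without wild-type replicate 1 and 245 without wild-type replicate 3. The 3 null libraries lay wholly above or below the 3 wild-type libraries for 11.1% of genes, where chance gives 10%. voom on the recovered reads also called 1 gene. The count was 0 without null replicate 1, 2 without wild-type replicate 2 and 5 without null replicate 3, when Rab3b, Dmrtb1, Gm10599 and Gm17167 joined Gm5859.

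Besides Dmrtb1, the genes of smallest p that were lower in null and kept by the naming rule did not pass the threshold. The leading 4 of them lay on chromosome 4. Rab3b, a small GTPase of regulated secretion, differed by -1.62 (SE 0.19, adjusted p = 0.112 in limma) and had 368, 399 and 366 reads against 142, 132 and 96. Slc24a2, a sodium, calcium and potassium exchanger, differed by -1.88 (SE 0.26). The lipid droplet protein gene Plin2 was at 6.01 ± 0.16 in wild type and 5.27 ± 0.15 in null (SD, n = 3), and Klhl9 differed by -0.45 (SE 0.09). Enpp6 on chromosome 8 differed by -0.86 (SE 0.21) and Aqp12, an aquaporin gene on chromosome 1, by -0.90 (SE 0.22).

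With the symbols passed over by the naming rule left out, Gm5859 among them, the genes of smallest p that were higher in null likewise missed the threshold. Cnpy1 differed by 1.76 (SE 0.26), with 14, 24 and 21 reads in wild type and 58, 65 and 73 in null. Bmp2, a bone morphogenetic protein gene, differed by 1.31 (SE 0.26). Junb, an AP-1 transcription factor gene, was at 1.68 ± 0.42 in wild type and 2.95 ± 0.23 in null (SD, n = 3). Cachd1 differed by 0.92 (SE 0.19), the nuclear receptor gene Nr4a1 by 1.05 (SE 0.24) and Chdh, which encodes choline dehydrogenase, by 0.70 (SE 0.19).

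Because a targeted allele can carry neighbouring chromosome with it, genes within 10 Mb of Dmrtb1 were compared with the rest. The 149 tested neighbours had a median change of -0.00 and did not move together in camera, and 0 passed the threshold in limma, with 1 gene called elsewhere. Within 5 Mb the 72 neighbours were lower than other genes in camera at its preset correlation (unadjusted p = 0.047), with a median of -0.02. Within 10 and 20 Mb the camera p was 0.385 and 0.687. An unadjusted p below 0.01 was found for 4 of the 149 neighbours, or 2.68%, and for 0.303% of other tested genes, an odds ratio of 9.06 (95% interval 2.35 to 25.2, two-sided Fisher's exact p = 0.00138). That comparison was chosen after the values were seen. Of the 4, 2 were higher and 2 lower in null. Without null replicate 2 the odds ratio was 1.89 and Fisher's exact p was 0.171. In that fit 2547 tested genes had an unadjusted p below 0.05, against 578 in the main fit.

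On the whole of chromosome 4, which held 6.92% of tested genes, lay 9 of the 10 genes of smallest p and 12 of the first 20. The 17 genes there with an unadjusted p below 0.01 fell into 2 regions. In the first, between 85 and 110 Mb, were Dmrtb1, Rab3b, Slc24a2, Plin2, Klhl9, the endothelial receptor gene Tek, Cachd1, 1700024P16Rik and 2210012G02Rik. In the second, between 41 and 43 Mb, were 8 predicted genes, all 8 higher in null, led by Gm5859, Gm10599 with 10, 6 and 15 against 211, 256 and 100 reads, and Gm17167 with 9, 10 and 21 against 182, 149 and 48. Gm10594 and Gm10597 in that region had identical reads in all 6 libraries, so these genes are not independent and their values are uncertain. None of the 169 tested genes in the gap between both, from 45 to 85 Mb, had an unadjusted p below 0.01.

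**Figure D2:**
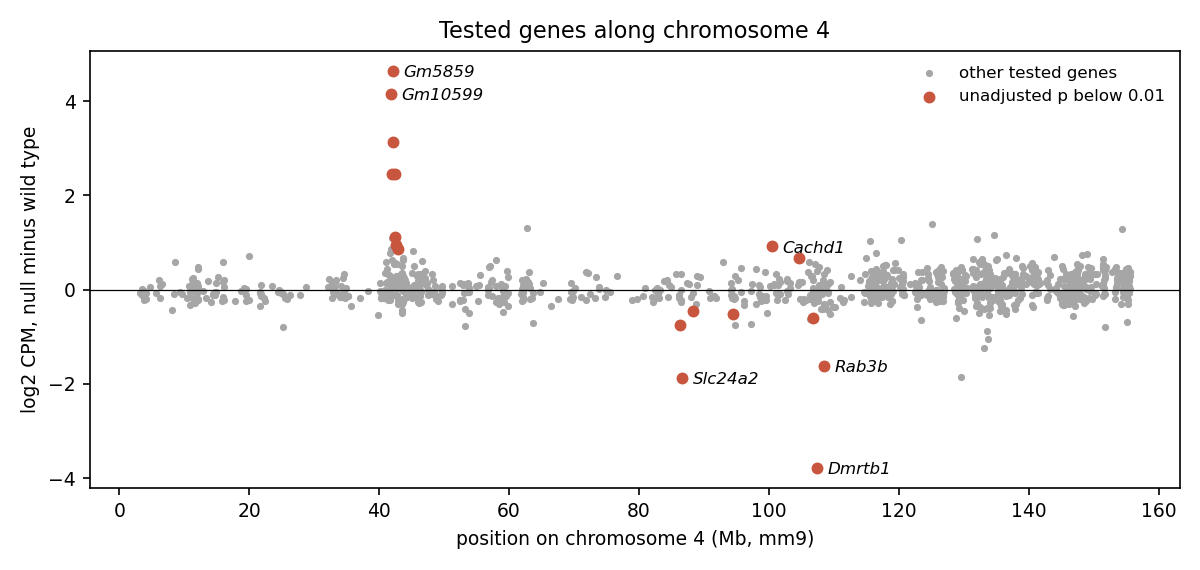
Change in log2 CPM, null minus wild type, of each tested gene against its position on chromosome 4 in Mb, with the 17 genes at an unadjusted p below 0.01 in red. They lie between 41 and 43 Mb and between 85 and 110 Mb, with Dmrtb1 the lowest point.

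Lists of blood cell and dividing-cell genes were lower in null under the preset correlation alone. All 5 tested members of the red blood cell list were lower, with a median change of -0.66, and the list fell in camera (adjusted p = 1.24e-05), a call lost at adjusted p = 0.516 with an estimated correlation. The globin genes Hbb-b2 (-0.71, SE 0.19), Hba-a2 (-0.73, SE 0.22), Hbb-b1 and Hba-a1 passed when adjusted over the list alone, 4 of 5 members, and 0 passed over all genes. Null replicate 3 was the farthest from the others, with a list score of -0.78 against -0.08 and -0.07 in null replicates 1 and 2, and without it the median was -0.43. Of the 14 macrophage and leukocyte genes all 14 were lower, with a median of -0.32, and the list fell (adjusted p = 8.19e-05, and adjusted p = 0.665 with an estimated correlation). Among them Tyrobp differed by -0.83 (SE 0.25) and the complement gene C1qb by -0.52 (SE 0.23), and 0 passed over all genes or adjusted over the list alone. The call was lost without wild-type replicate 1 (median -0.12, adjusted p = 0.0821).

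The mitotic cell cycle list fell slightly, with 21 of 28 members lower and a median of -0.16 (camera adjusted p = 2.11e-05, and adjusted p = 0.516 with an estimated correlation). Its leading members were Rrm2, a subunit of ribonucleotide reductase, at -0.49 (SE 0.13), the spindle motor gene Kif11 at -0.31 (SE 0.09), the cyclin gene Ccnb2 at -0.35 (SE 0.12) and the proliferation marker Mki67 at -0.27 (SE 0.09). None of the 28 passed over all genes or adjusted over the list alone, and 9 had an unadjusted p below 0.05 in limma. The list score was -0.18 in null replicate 2 and -0.01 and 0.00 in null replicates 1 and 3, against 0.04 to 0.10 in wild type, and without null replicate 2 the call was lost (median -0.15, adjusted p = 0.0679). The immediate early genes rose as a list, 11 of 14 higher with a median of 0.30 (adjusted p = 0.00813, and adjusted p = 0.665 with an estimated correlation). Junb and Nr4a1 passed when adjusted over the list alone, whereas Egr1 at 0.54 (SE 0.24) and Fos at 0.92 (SE 0.48) did not. This call was lost without wild-type replicate 3 (median 0.16, adjusted p = 0.0794) and without null replicate 2 (adjusted p = 0.0676), and with array weights the median was 0.04. Wild-type replicate 3 had the lowest score of the 6 libraries on this list, -0.49. Null replicate 2, at 0.16, lay between null replicates 1 and 3, at -0.01 and 0.40.

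**Figure D3:**
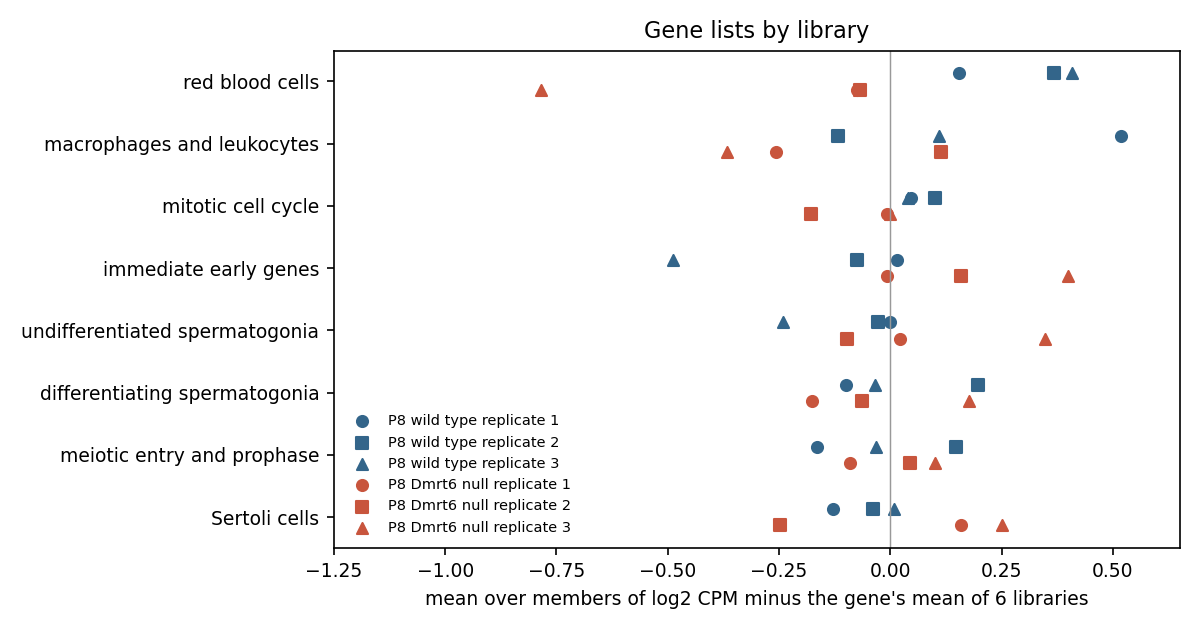
Mean over the members of a list of log2 CPM minus each gene's mean over 6 libraries, for 8 lists, 1 point per library. Null replicate 3 stands apart on the red blood cell list at -0.78 and wild-type replicate 3 on the immediate early list at -0.49.

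The germ cell lists did not pass. Of 23 differentiating spermatogonia genes 16 were higher in null, with a median of 0.12 but a mean of -0.04 that includes Dmrtb1 (camera adjusted p = 0.36). The receptor gene Kit differed by 0.35 (SE 0.13), and the transcription factor genes Sohlh1 and Sohlh2 by 0.40 (SE 0.14) and 0.28 (SE 0.10). Undifferentiated spermatogonia genes had a median of 0.09 (adjusted p = 0.13), with Neurog3 at 0.60 (SE 0.20), Lin28a at 0.43 (SE 0.16), Lhx1 at 0.73 and Zbtb16 at 0.45. Meiotic entry and prophase genes divided 22 higher and 19 lower, with a median of 0.00 (adjusted p = 0.864), and the leading members went both ways: Mei1 (0.51, SE 0.20) and Stag3 (0.21, SE 0.13) were higher, Psmc3ip (-0.24) and Hormad1 (-0.23) lower. With array weights this list passed as lower (median -0.10, adjusted p = 0.0218). The piRNA pathway list was at 0.15 (adjusted p = 0.0564), with Tdrd9 at 0.55, Mov10l1 at 0.33 and Piwil2 at 0.25 higher and Gtsf1 at -0.30 lower. Pachytene and later genes had a median of 0.12 (adjusted p = 0.36), and p53 targets one of 0.13 (adjusted p = 0.0958), with Sesn2 at 1.08 (SE 0.34), Btg2 at 0.29 (SE 0.10) and Bax at 0.21 higher and Pmaip1 at -0.33 lower. With only genes at a mean log2 CPM of at least 2, which leaves out Dmrtb1, the differentiating list passed (median 0.25, adjusted p = 0.0295), as did the piRNA (adjusted p = 0.0399) and p53 lists (adjusted p = 0.044). The undifferentiated list passed without wild-type replicate 1 (adjusted p = 0.0227), the piRNA list without wild-type replicate 2 (0.00176) or null replicate 3 (0.0436), and the p53 list without null replicate 3 (0.0246), when 7 lists passed in all.

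Somatic and other lists also stayed short of the threshold. Adjusted p was 0.36 for Leydig cells (median -0.01, with Hsd3b1 at -0.38 and Hsd17b3 at -0.45), endothelial cells (-0.12), core histones (-0.12) and Y-linked genes (-0.09), and 0.386 for the retinoic acid pathway (0.09). It was 0.516 for Sertoli cells (0.07), 0.664 for peritubular and stromal cells, 0.755 for X-linked germ cell genes, and 0.864 for the DMRT family and for epididymis and rete. The median and the test disagreed in sign for peritubular and stromal cells (median 0.02, lower in the test), X-linked germ cell genes (0.00, lower), and epididymis and rete (-0.01, higher). Sertoli cells (median 0.25, adjusted p = 0.00366) and peritubular and stromal cells (-0.28, adjusted p = 0.00945) passed without null replicate 2, and endothelial cells without null replicate 3 (-0.15, adjusted p = 0.00511). With array weights these 3 passed as well (0.19, -0.30 and -0.32). The DMRT family had a median of 0.18 and a mean of -0.29 that includes Dmrtb1, with Dmrt1 at 0.35 (SE 0.26). The libraries did not separate by genotype on the main axis of variation, which took 44.8% of the variance: null replicate 3 lay at 54.3 and the other libraries between -20.2 and 1.68.

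DMRT6 peaks in adult testis were short and spread over all 21 chromosomes. The median width was 176 bp (56 to 1606) and the median score 94.7 (50.02 to 3100, with 7 peaks at the highest score). The 10 peaks of highest score included 1 on chromosome 8 from 23969741 to 23970148, 63 bp upstream of the 5' end of the histone acetyltransferase gene Myst3, and 1 on chromosome 8 from 109817089 to 109817482, 85 bp upstream of Nfat5, both at 3100. Others at 3100 lay inside Anks1 (chromosome 17, 28136589 to 28137199) and Atp8a1 (chromosome 5, 68138681 to 68139393), 30790 bp from the 5' end of Mcfd2 (chromosome 17, 87634277 to 87634694), 42291 bp upstream of the calcium pump gene Atp2a2 (chromosome 5, 122994244 to 122994704) and 4238 bp from that of Gm6905 (chromosome 7, 130157655 to 130158074). The next 3, at 2996, 2873 and 2720, lay 16434 bp from the 5' end of 2410004B18Rik (chromosome 3, 145616922 to 145617903), 171103 bp from that of Cenpf (chromosome 1, 191340673 to 191341051) and 208 bp inside Zfp341 (chromosome 2, 154438940 to 154439543).

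Peaks lay near gene starts far more often than random placements. Their middles were within 1 kb of a 5' end for 2724 of 14862 peaks, 18.3% (exact 95% binomial interval 17.7 to 19.0), where 100 random placements averaged 1.71% and reached at most 1.94% (permutation p = 0.0099, the smallest 100 draws can give). In the lowest of 5 equal groups by score 28.7% of peaks lay that close to a start, and in the highest 12.8%. The middle lay inside a gene body for 50.1% of peaks.

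Dmrtb1 carried 3 peaks within 10 kb of its own 5' end: 107356816 to 107356987 at 66 bp upstream with a score of 161, 107355477 to 107355865 at 1164 bp inside the gene with 291, and 107359848 to 107359986 at 3082 bp upstream with 109 (rounded scores). Sohlh2 had 1 peak 533 bp upstream (chromosome 3, 54985267 to 54985568, score 343) and Dmrt1 had 1 at 81 bp upstream (chromosome 19, 25579883 to 25580172, score 56.9), close to the lowest score of the list. Kit, Sohlh1 and Stra8 had no peak within 10 kb, with the nearest at 124, 11.4 and 21.7 kb. Among the 12 genes of smallest p kept by the naming rule, 6 per direction, Chdh had a peak 330 bp inside and Nr4a1 one 7252 bp upstream. The others had none within 10 kb, nor had Gm5859. Of other list members named, Egr1 lay 17 bp from the nearest peak, Psmc3ip 66, Sesn2 636 and Neurog3 3258.

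**Figure D4:**
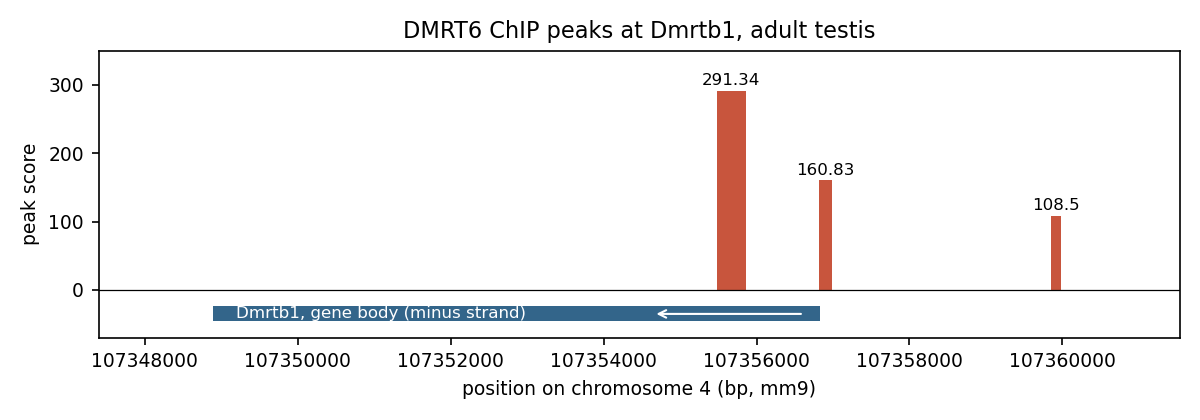
Peaks of the adult testis ChIP around Dmrtb1 on chromosome 4, in bp of mm9, each drawn from its start to its end with its score as height, above the gene body on the minus strand. The peak of score 291.34 lies inside the gene and those of 160.83 and 108.5 at and upstream of its 5' end.

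Peaks were sparse on the X chromosome. It held 182 peaks over 163 Mb, 1.11 per Mb (exact 95% Poisson interval 0.958 to 1.29), where the 19 autosomes ranged from 4.47 per Mb on chromosome 3 to 9.44 on chromosome 11. The Y chromosome held 9 peaks over the 2.84 Mb between its first and last feature.

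**Figure D5:**
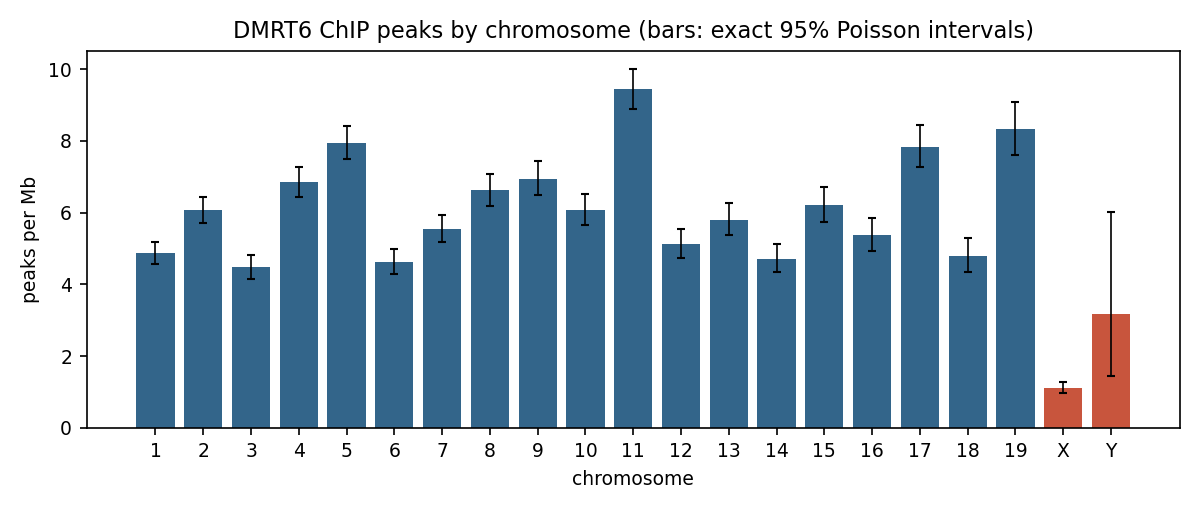
Peaks per Mb on each chromosome, with exact 95% Poisson intervals as bars. The X chromosome stands at 1.11 per Mb and the lowest autosome, chromosome 3, at 4.47.

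Adult binding was then set beside expression at P8, a different stage. Of the tested genes 5198, or 31.2%, had a peak within 10 kb, from 20.9% in the lowest of 5 equal groups by expression to 38.4% in the highest. The single gene past the threshold was not among them, and 1 gene is too few to test. Bound genes as a set had a median change of 0.04, a difference of 0.04 from other genes that did not pass in camera (p = 0.0533, and p = 0.104 with an estimated correlation). It passed for peaks over the gene body (difference 0.08), for peaks within 50 kb, for the stricter peak scores, with array weights, at a mean log2 CPM of at least 2 and without null replicate 2 (difference 0.07). Without null replicate 3 the difference was 0.02.

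Among the fixed lists, a comparison chosen after the files were seen, Sertoli cell genes were bound less often than other tested genes, 2 of 31 or 6.45% (odds ratio 0.151, Fisher's exact adjusted p = 0.0305 over 20 lists). The bound members were Amh and Sox8. X-linked germ cell genes were bound in 0 of 15 (adjusted p = 0.046), which restates the sparse X peaks: of the 834 other tested X genes 5.28% were bound (two-sided Fisher's exact p = 1 against these). On the list named core histones 4 of 5 genes were bound: Hist1h3b, H2afx, H2afz and the linker histone gene Hist1h1c. DMRT family genes were bound in 5 of 8, Dmrt1, Dmrt2, Dmrtb1, Dmrtc1a and Dmrtc2. Neither list passed the threshold (Fisher's exact adjusted p = 0.238 and 0.472).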

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

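The voom fit and the comparison of genes with an unadjusted p below 0.01 near Dmrtb1 were chosen after the data were seen. Unless a cause is given, the cause of a change was not tested. The edgeR and DESeq2 alternatives planned for recovered counts were left out, not run, although whole reads were recovered and voom used them, and the motif alternatives were not run for want of a genome.

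The count of genes past the threshold, 1, became 3 with no filter, 0 at a mean log2 CPM of at least 2 (Gm5859 is then not tested), 2 with quantile normalization, 3 with median centring, 136 with array weights, 3 at an adjusted p of 0.1, and 0 to 5 without 1 library. Dmrtb1 kept its direction throughout and passed with no filter (-3.78), quantile normalization (-3.92), median centring (-3.83), array weights (-4.46) and without null replicate 3 (-3.96), the only library whose removal let it pass, and over all 6 removals it ranged from -4.00 to -3.45. It is not tested at a mean of at least 2. Array weights gave null replicate 1 a weight of 19.3 and the others at most 1.46, so that fit rests largely on 1 null library.

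The number of lists past the threshold, 4, became 7 at a mean of at least 2, 7 with array weights, 0 with an estimated correlation, 0 with fry and 3 to 7 without 1 library. Fry tests whether a list moves on balance, not against other genes, and gave adjusted p of 0.408 for red blood cells (median -0.66) and the mitotic cell cycle (-0.16), and 0.668 for macrophages and leukocytes (-0.32) and immediate early genes (0.30). With an estimated correlation these were 0.516, 0.516, 0.665 and 0.665. Without 1 library the medians were -0.83 to -0.43 for red blood cells, -0.21 to -0.14 for the mitotic list, -0.42 to -0.12 for macrophages and leukocytes, and 0.13 to 0.45 for immediate early genes, whose median with array weights was 0.0442. Meiotic entry and prophase turned to lower and passed with array weights (-0.10, adjusted p = 0.0218, over a range of 0.0218 to 0.978 for its alternatives).

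Genes past the threshold within 10 Mb of Dmrtb1 numbered 8 with array weights and 0 to 1 without 1 library. The odds ratio for an unadjusted p below 0.01 there ran from 1.89 to 14.7 without 1 library and was 1.75 with array weights. With array weights 31 of the 136 genes past the threshold lay on chromosome 4, which held 6.92% of tested genes. The difference between bound and other genes passed at a mean of at least 2 (0.0454), with array weights (0.042), for peaks within 50 kb (0.0669), over the gene body (0.0794), at or above the median score (0.057) and with a score of at least 100 (0.0592), and ran from 0.0169 to 0.0736 without 1 library.

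The set at or above the median score holds 7432 peaks and a score of at least 100 leaves 6869. The share near a 5' end was 30.7% within 5 kb (7.94% at random), 39.8% within 10 kb (14.6% at random), 15.3% at or above the median score and 15.3% at a score of at least 100.

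The replicate numbers do not pair the libraries: the deviations of same-numbered libraries correlated at -0.09, -0.22 and -0.04, and 0 of 6 libraries correlated best with its own number. With a replicate block 2 genes passed, Gm5859 and Dmrtb1 (-3.78, adjusted p = 0.0269), and the 4 lists passed as before. Depth differs little between libraries, 23.8 to 29.0 M reads, and the low level of Gm5859 and Dmrtb1 limits what their folds can show.

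Alternatives taken as no change numbered 9 for Dmrtb1, 8 for the count of genes and 13 for the count of lists. They numbered 16 for the genes near Dmrtb1 and 15 for bound genes. A single value was taken so if it kept its sign and its side of the threshold. A count was taken so if it was equal or close, whichever genes or lists made it up. Over the 89 genes named by rule besides Dmrtb1, alternatives of no change numbered 1385, with 16 stronger, 1 weaker and 13 reversed. Of these genes only Gm5859 passed in the main fit, so no change mostly meant that a gene stayed short of the threshold. The reversals fell on 6 genes that passed in no alternative, which ranged from -0.34 to 0.62 (Aqp1), -0.32 to 0.25 (Hist1h2bc), -0.61 to 0.04 (Pax8), -0.50 to 0.14 (Hist1h3b), -0.54 to 0.25 (Defb42) and -0.42 to 6.28 (Crisp1). Over all lists such alternatives numbered 298, with 13 stronger, 13 weaker and 1 reversed. A list that passed in neither fit was taken as no change even where its sign turned.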

Other observations

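The tests of explanations in this part were chosen after the result they bear on had been seen, although the fits without 1 library and with an estimated correlation were planned.

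A few transcripts were all but missing from a single library. Crisp1, a secretory protein gene of the epididymis and the leading member of the epididymis and rete list, had 2432 and 2751 reads in wild-type replicates 1 and 2, 0 in wild-type replicate 3 (which allows up to 3 reads), and 2712, 3077 and 871 in null replicates 1, 2 and 3. A search over all genes, made after this was seen, asked which had under 10% of the median of the other libraries in 1 library, where that median was at least 100 reads and no other library fell below 0.3 of it. It found 6 genes, all in wild-type replicate 3: Crisp1, Spink8 with 3 reads, Cldn8 with 8, 2300002M23Rik with 10, Npy6r with 6 and the beta-defensin gene Defb29 with 5. The other 5 libraries had 473 to 1905 reads for Spink8. Cdh16, looked up after this was seen, was also low in wild-type replicate 3, with 209 reads against 555 to 2070 elsewhere. Other members of the epididymis and rete list did not follow: wild-type replicate 3 had 247 reads of Defb42 (189 to 600 elsewhere), 258 of Aqp1 (202 to 610) and 211 of Pax8 (117 to 376), and the list did not pass (adjusted p = 0.864). The cause was not tested.

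Genes high in 1 library alone, at least 100 reads and over 10 times any other, numbered 3. The neutrophil granule genes Mpo and Ctsg had 194 and 127 reads in wild-type replicate 1 and at most 5 and 2 elsewhere. This is the library without which the macrophage and leukocyte list lost its call. Rdh16 had 108 reads in null replicate 2 and at most 10 elsewhere. The fat cell genes Adipoq and Car3, named after their values were seen, were not confined to 1 library: Adipoq had 334, 79 and 166 reads in wild type and 15, 31 and 54 in null (log2 change -2.46, adjusted p = 0.755), and Car3 2582, 388 and 1229 against 90, 195 and 454.

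The genes around Dmrtb1 with an unadjusted p below 0.01 may mark a strain segment that travelled with the targeted allele, although the labels give one strain background for all 6 P8 libraries. The window of 10 Mb was set before the data were examined, but the cut at an unadjusted p below 0.01 was chosen after the values were seen. The odds ratio of 9.06 within that window therefore cannot decide for such a segment. It was 1.89 without null replicate 2 and 1.75 with array weights. DMRT6 binding at the starts of these genes is not decided: 0 of 8, Dmrtb1 left out, had a peak within 10 kb against 31.2% of tested genes (Fisher's exact p = 0.0639), and an effect of the allele itself on its neighbours was not tested. The real grouping gave 4 such genes within 10 Mb and the highest of the other splits gave 1. Only 1 of 10 splits, the real one itself, was as high. The 10 splits are too few for a share under 0.05.

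Whether the 8 genes between 41 and 43 Mb lie on one segment with them stays open: the test between 45 and 85 Mb against 10 Mb around Dmrtb1 (Fisher's exact p = 0.0472) decides nothing, since that window was drawn as the gap between both groups. Reads counted for more than one near-identical copy remain open too: 4 of the 8 had another gene in the window within 0.3 log2 units in every library, whereas Gm5859, Gm10599, Gm17167 and Gm12429 had none. A further 5 genes of the window had at most 20 wild-type reads in all and at least 100 null reads, such as Gm13300 with 9 against 364 and Gm13301 with 4 against 282. The counts of the neighbouring chemokine genes did not follow, with 711, 609 and 608 reads of Ccl21b in wild type and 533, 1003 and 534 in null. Ccl21c had nearly the same reads, 716, 606 and 615 against 536, 1004 and 537. If such reads are shared between copies, these counts cannot show whether 1 copy changed. A separate inherited difference in this region, in copies present or transcribed, is a candidate explanation that was not tested.

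For the 4 lists that passed, the calls at the preset correlation stayed without null replicate 3 (highest adjusted p in camera 0.0436). That cannot exclude a cause in this library, since the same preset calls lists under most splits of the libraries, as given below. Members of these lists did vary together among libraries, beyond the preset correlation of 0.01. The estimated correlation was 0.91 for red blood cells and 0.74 for macrophages and leukocytes. It was 0.38 for immediate early genes and 0.14 for the mitotic list. With it the lowest adjusted p of the 4 in camera was 0.516. That setting raised p even where members did not vary together. The p53 list, at an estimated correlation of -0.03, went from an unadjusted camera p of 0.0287 to 0.0763. The lost calls therefore cannot be credited to members varying together alone, which remains a candidate explanation of the calls. The real grouping called 4 lists and the highest of the other splits 11. At least as many were called by 8 of 10 splits, the real one included, and 10 splits are too few for a share under 0.05. The split of 11 set wild-type replicates 1 and 3 and null replicate 1 against the rest, and no test separated members that vary together from a structure of the samples. A biological effect of the null genotype on blood content or cell division stays open and was not separated from these.

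Whether a single X per male cell accounts for the sparse X peaks stays open. The comparison made here assumes that a single copy in place of a pair takes a score of 100 to about the lowest, 50.02. The scale of the score is not stated, so a larger fall cannot be excluded. X peaks of any score stood at 1.11 per Mb (up to 1.29), below peaks with a score of at least 100 on the sparsest autosome for these, chromosome 1, at 2.09 (from 1.90), and only at a score of 155 did the sparsest autosome come down to the X. The X had 0.214 peaks per gene tested at P8 (up to 0.248) and each autosome at least 0.683 (from 0.638), but the peaks are from adult testis, where expressed X genes were not counted, so few expressed genes stay open. How well reads map to the X was not tested, and closed X chromatin in meiotic cells is a biological hypothesis that these data did not test.

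Other splits of the 6 libraries called at most 0 genes where the real one called 1, so that 1 of 10 splits, the real one itself, called as many. The difference between bound and other genes was 0.0443 in the real grouping and up to 0.0606 in the others, with 4 of 10 splits, the real one included, as large. In both cases 10 splits are too few for a share under 0.05. One split, with wild-type replicates 1 and 3 and null replicate 2 together, gave 355 genes at an unadjusted p below 0.01 where the real one gave 55.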
